A study of Rattus norvegicus with 8 samples.

How the data were processed

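RNA from rat amygdala punches was compared on 8 Agilent rat oligonucleotide arrays that read 2 channels each, green (Cy3) and red (Cy5). On 4 arrays RNA of rats trained in conditioned taste aversion (CTA) was set against RNA of flavor only rats, and on the other 4 against RNA of toxin only rats. Per the labels, each channel held labelled cRNA made from 500 ng of RNA pooled from 3 rats, and each of the 4 replicates used new rats, 12 per group. CTA RNA was in Cy3 in replicates 1 and 3 and in Cy5 in replicates 2 and 4 of both comparisons, so each comparison held both dye orientations equally.

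Per the file headers, the deposited scanner tables give intensity values per spot, as mean spot brightness and median local background in each channel, written by Agilent Feature Extraction 7.5.1. The submitters' processing notes name version 5.1 of the same software and limma, and this difference between header and notes was left open. The same tables hold the scanner software's processed intensity values, background subtracted and dye normalized per the file headers, and their log10 ratio of red over green. The authors also deposited a table of log2 ratios for the same arrays, with scale, centring and direction unstated. Set against the scanner values, these were log2 ratios of CTA over control on every array, with column medians from -0.0117 to 0.0037. They matched loess normalized ratios without background subtraction with r of at least 0.99999 across probes and a median absolute difference of at most 0.000637 per array. Which software options gave the authors' values is not stated.

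The starting values were mean signals, corrected for background with normexp (offset 50) on the median local background and normalized within each array by loess, with control spots at weight 0. Spots marked non-uniform by the scanner software were left out. No scaling between arrays was applied. Of the non-control probes, 19695 were well above background in either channel on at least 4 of the 8 arrays and were tested. limma 3.58.1 in R 4.3.3 fitted all 8 arrays together, with 1 column for CTA over flavor only, 1 for CTA over toxin only and 1 for the dye, which left 5 residual degrees of freedom. The difference of the first 2 columns is toxin only over flavor only, compared through the CTA channels. Tests were two-sided and Benjamini-Hochberg adjusted over all tested probes, and a probe was called at an adjusted p under 0.05. Positive log2 ratios mean higher in CTA, or higher in toxin only in the indirect comparison. An SE is limma's moderated standard error from this fit, with a probe's variance pooled over both comparisons and drawn toward that of other probes. It is not the spread of the 4 arrays of a comparison, which is given as SD where shown. For Fen1, the gene named in the title of the series, an exact two-sided sign-flip permutation test over the 4 arrays was added, whose smallest possible p is 0.13.

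Probes were named by matching the accession of each probe to a table of rat genes of the GRCr8 assembly, which named 3757 probes. Another 99 were named from a symbol in the probe's own description, and 16644 had no gene symbol. No coordinates are given, because the arrays name no genome build. Where several probes name a gene, the brightest on average stood for it. Only 3585 genes with a symbol could enter the gene lists, so genes outside them were seen as single probes only.

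In all, 26 gene lists were fixed: immediate early genes, DNA repair and replication, glucocorticoid responsive genes, lithium, inositol and GSK3 targets, osmotic stress, heat shock and chaperones, glutamate receptors and postsynaptic density, the GABA system, neuropeptides, monoamine and cannabinoid receptors, cytokine and NF-kB response, oxidative phosphorylation, ribosomal proteins and the circadian clock, and markers of neurons, astrocytes, oligodendrocytes, microglia, endothelium and mural cells, blood, choroid plexus and ependyma, meninges and fibroblasts, striatum, hypothalamus, thalamus, and cortex and hippocampus. Each list was compared with the other named genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. A camera test with an estimated correlation and limma's fry stood beside it. The set tests took the 3061 genes with no missing value, which left out 524. Lists with under 5 such genes, which were the circadian clock, microglia, blood and meninges lists, are given as values without a set test. Members of each list were also adjusted over the list alone.

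The genes named are set by a rule: in each comparison, those called with the same sign on all 4 arrays, up to 12 in each direction. Where fewer pass, the list is filled to 6 per direction by the smallest unadjusted p among genes of the same sign on all 4 arrays, and these are given as values that did not pass. Fen1 and up to 4 members of each gene list were added by the same rule, and some of these members are not reported here. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Probes outside the rule are said to have been chosen after their values were seen.

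The file headers give 3 days on which the array images were read by the software: 1 for the replicate 1 arrays, 1 for the replicate 2 arrays and 1 for the 4 arrays of replicates 3 and 4. Each day held both comparisons, so values with the day as a block and within each day could be given. Same-numbered arrays of the 2 comparisons deviated from their group means together, with correlations across probes of 0.471, 0.563, 0.412 and 0.417, so the replicate number was taken as a pairing in alternative fits. The main fit held no block, so its values ignore any such pairing. The labels do not say that same-numbered arrays share a CTA pool, and these arrays also share the dye orientation and the image day. With the dye effect removed the correlations were -0.0414, 0.198, 0.0424 and 0.409. The blocked fit used limma's duplicateCorrelation, with a consensus correlation of 0.306 for the number and 0.258 for the day.

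The alternatives were other background and normalization methods, the authors' values, other filters on dim probes, fits without the dye term, with array weights, with blocks, with a trended robust variance or with only 1 comparison's arrays, other thresholds, and each array left out in turn. Keeping spots marked non-uniform, using only replicates 3 and 4, comparing lists with all tested probes, wider gene naming, leaving out both arrays of a replicate number and leaving Sgk1 out of the lists were chosen after seeing the data.

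The methods were tested on simulated data with the variances of the 19695 probes. For CTA over flavor only, 92 of 100 probes with a true log2 change of 0.5 were called, all 100 with a change of 1 and all 100 with a change of 2, with 13 unchanged probes called. For CTA over toxin only the same counts were 90, 100 and 100, with 32 unchanged probes called. These 32 are a larger share of the calls than an adjusted p under 0.05 is meant to allow, so false calls were not held to that share in this simulation. In a simulation of the 3585 genes for CTA over flavor only, a list moved by a log2 of 0.2 was called with an adjusted p of 1.2e-20 and 0 of 25 unmoved lists were called. These simulations drew genes independently and so say nothing of correlated genes or batches. They also planted many changed probes at once, which makes the adjusted threshold easier to reach, and drew normal noise. In the real data a probe at 1.01 and Sgk1 at 0.95 in CTA over flavor only were not called (limma adjusted p = 0.0686 and 0.249). The absence of calls therefore does not exclude changes of these sizes.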

Results

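Conditioned taste aversion (CTA) is a form of learning in which an animal avoids a flavor that was followed by sickness. Male Long Evans rats drank 0.1% dextrose, the new flavor, for 10 min and were injected 40 min later with lithium chloride (LiCl, 100 mg/kg), which makes rats ill. Flavor only rats had the dextrose and an injection of saline, and toxin only rats had water and LiCl. Punches of the amygdala, a brain region needed for aversive learning, were taken 3 h after training. The RNA of CTA rats was compared on 4 arrays with that of flavor only rats and on 4 arrays with that of toxin only rats, each channel holding a pool of 3 rats.

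The median signal per array was 2.68 to 9.89 times the local background in the green channel and 2.60 to 5.64 times in the red. Between 16691 and 20243 probes were well above background in green and between 17327 and 20161 in red. The standard deviation of log2 ratios over probes ranged from 0.14 on the toxin only replicate 1 array to 0.38 on the flavor only replicate 2 array. The number of arrays limits the precision of each value.

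The comparison with flavor only rats asks what LiCl after the flavor adds to the flavor alone. In it CTA rats had more Sgk1 RNA on each of 4 arrays. The log2 ratio was 0.95 ± 0.15 (limma SE), which is 1.94-fold, with an SD of 0.44 over the 4 arrays. Sgk1 encodes a kinase induced by glucocorticoids and by cell shrinkage. Oligodendrocyte markers as a list lay higher in CTA and ribosomal protein genes lower, though neither list was called with an estimated correlation (adjusted p = 0.530 for each) or by fry (0.375 and 0.348). No single probe passed the adjustment over all 19695 probes, and the adjusted p of Sgk1 was 0.249 (limma). In the same limma fit 1848 probes had an unadjusted p under 0.05, 723 higher and 1125 lower in CTA, where chance alone gives about 985. That count was 825 without flavor only replicate 2, 986 without replicate 3, 3225 without replicate 4, 1042 with scaling between arrays, 1044 with the scanner log ratio and 1049 without the dye term.

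Among genes with a symbol, the rule for named genes also gave some with positive log2 ratios. They were Ddit4, an inhibitor of mTOR signalling (0.51 ± 0.11), Cryab, a small heat shock protein (0.49 ± 0.11), and Slc2a1, the glucose transporter of the blood-brain barrier (0.42 ± 0.10). Nherf2, a scaffold of sodium-hydrogen exchangers (0.36 ± 0.10), and Ralgds, an activator of Ral GTPases (0.32 ± 0.08), were named as well. Those with negative log2 ratios were S100a6, the calcium-binding protein calcyclin (-0.57 ± 0.12), Megf6, a protein with EGF-like domains (-0.46 ± 0.12), Cxcl10, an interferon-induced chemokine (-0.44 ± 0.10), Zng1a, a zinc chaperone (-0.39 ± 0.10), Tacr3, the receptor of neurokinin B (-0.38 ± 0.08), and Casp1, the inflammasome protease (-0.36 ± 0.09). Errors are limma SE from the fit of both comparisons together. All 11 genes had the same sign on 4 of 4 arrays, and the limma adjusted p was 0.530 for each. Some probes without a symbol, chosen after their values were seen, had smaller unadjusted p-values in limma than these 11 genes. They included A_42_P813742 (0.67 ± 0.10), A_42_P731280 (0.62 ± 0.09), A_43_P11044 (-0.45 ± 0.08) and A_42_P777494 (-0.42 ± 0.07), and none of these passed the adjustment. Within image days, Sgk1 was at 1.16 on day 1, 1.15 on day 2 and 0.75 on the 2 arrays of day 3. Ddit4 was at 0.96, 0.53 and 0.28 on the same days and S100a6 at -0.67, -0.68 and -0.46. Over the alternatives the signs stayed, which choosing genes with the same sign on 4 of 4 arrays largely fixed. The sizes moved, from 0.28 to 0.65 for Ddit4, 0.19 to 0.66 for Nherf2, -0.93 to -0.31 for Cxcl10, -0.80 to -0.31 for Megf6, -0.64 to -0.23 for Casp1 and -0.48 to -0.24 for Zng1a. The last 4 were dim, at mean log2 intensities of 6.76 for Cxcl10, 6.86 for Megf6, 6.98 for Casp1 and 6.95 for Zng1a. The mean over all genes with a symbol was 7.98.

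The smallest adjusted p, 0.0686, belonged to a probe chosen after its value was seen, A_42_P480224, described as rat glycerol 3-phosphate dehydrogenase, an enzyme of glycerol lipid synthesis. Its log2 ratio was 1.01 ± 0.11 (limma SE), positive on 4 of 4 arrays, with an SD of 0.41 over them. With the replicate number as a block it was the 1 probe called in this comparison (limma adjusted p = 0.0469), and with the image day as a block likewise (adjusted p = 0.0148). A dimmer probe matched by accession to Gpd1, a gene of the same enzyme name, was at -0.02 ± 0.09, so the probes disagree. Without the flavor only replicate 3 array, Sgk1 was the 1 probe called, at a log2 ratio of 1.21 and an adjusted p of 0.0126.

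Of 22 gene lists tested, camera called 5 in CTA against flavor only rats, and none was called with an estimated correlation or by fry. The ribosomal protein genes, which encode the protein part of ribosomes, were lower for 34 of 37 members with a median log2 ratio of -0.14 (adjusted p = 1.5e-06, and adjusted p = 0.530 with an estimated correlation). Rpl32 was at -0.35 ± 0.10, and 0 members passed when adjusted over the list alone or over all genes (limma), with 5 at an unadjusted p under 0.05. The list median was -0.28 on day 1, -0.23 on day 2 and -0.04 on day 3. On the arrays of replicates 1 to 4 it was at -0.28, -0.23, -0.11 and 0.04, where the oligodendrocyte markers were at 0.73, 0.21, 0.23 and -0.11. The adjusted p was 2.2e-05 with the day as a block and 0.575 in replicates 3 and 4 only.

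The oligodendrocyte markers, genes of the cells that make myelin, were higher for 14 of 14 members with a median of 0.29 (adjusted p = 2.9e-06, and adjusted p = 0.530 with an estimated correlation). Aspa (0.40 ± 0.12), Mag (0.36 ± 0.12) and Mog (0.32 ± 0.11) had the smallest p-values. In the limma fit 0 members passed when adjusted over the list alone or over all genes, and 5 had an unadjusted p under 0.05. By day the list median was 0.73, 0.21 and 0.06, with an adjusted p of 2.2e-05 with the day as a block and 0.3004 in replicates 3 and 4 only. Without the flavor only replicate 1 array it was 0.0498.

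Osmotic stress genes, which adjust cell volume and water balance, were higher for 9 of 12 members with a median of 0.16 (adjusted p = 0.00819, and adjusted p = 0.484 with an estimated correlation). Adjusted over the list alone 2 rose, Sgk1 and Slc2a1, against 0 over all genes (limma), and 4 were higher at an unadjusted p under 0.05. Slc12a2, a sodium, potassium and chloride cotransporter, was at 0.32 ± 0.12. Glucocorticoid responsive genes were higher for 9 of 14 members with a median of 0.07 (adjusted p = 0.00819, and adjusted p = 0.530 with an estimated correlation). Adjusted over the list alone 3 rose, Sgk1, Ddit4 and Slc2a1, against 0 over all genes, with 4 higher at an unadjusted p under 0.05. Sgk1 and Slc2a1 are in both lists, and without Sgk1 neither list was called (adjusted p = 0.0905 for each). Some probes, chosen after their values were seen, had no gene symbol and so entered neither list. They are described as glycerol 3-phosphate dehydrogenase (1.01), FK506 binding protein 5 (0.68 and 0.21) and BTE binding protein (0.50). The glucocorticoid list was fixed with Gpd1, Fkbp5 and Klf9, genes that go by these names, and the osmotic list with Gpd1. The lists took the Gpd1 probe at -0.02 and the Klf9 probe at 0.24. By day the osmotic list was at 0.34, 0.09 and 0.09 and the glucocorticoid list at -0.01, -0.03 and 0.16. On the arrays of replicates 1 to 4 the osmotic list was at 0.34, 0.09, 0.12 and 0.07. The oligodendrocyte markers were at 0.73, 0.21, 0.23 and -0.11 there. The glucocorticoid list was at -0.01, -0.03, 0.16 and 0.17, and the cortex and hippocampus markers at 0.04, 0.05, 0.24 and 0.14. These marker lists were picked after their values were seen. With the day as a block the adjusted p was 0.00799 and 0.00259. Without the flavor only replicate 4 array neither list was called (0.0586 and 0.730). On that array the striatum markers were at -0.49, against -0.05 to 0.11 on the other flavor only arrays.

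Genes of the cytokine and NF-kB response were lower for 18 of 24 members with a median of -0.11 (adjusted p = 0.00353, and adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone 2 fell, Cxcl10 and Psmb9, a subunit of the immunoproteasome (-0.40 ± 0.10, on 3 arrays), against 0 over all genes. Vcam1, an adhesion molecule of blood vessels, was at -0.28 ± 0.09. The list was at -0.0012, -0.25 and -0.09 on the 3 days, and without the flavor only replicate 2 array it was not called (adjusted p = 0.272). On the arrays of replicates 1 to 4 it was at -0.0012, -0.25, -0.14 and -0.03, and the markers of meninges and fibroblasts, lower for 7 of 7 genes and too few for a set test, were at -0.05, -0.69, -0.70 and -0.02. Heat shock and chaperone genes were not called as a list (adjusted p = 0.819), but adjusted over the list alone 1 of 15 rose, Cryab.

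**Figure D1:**
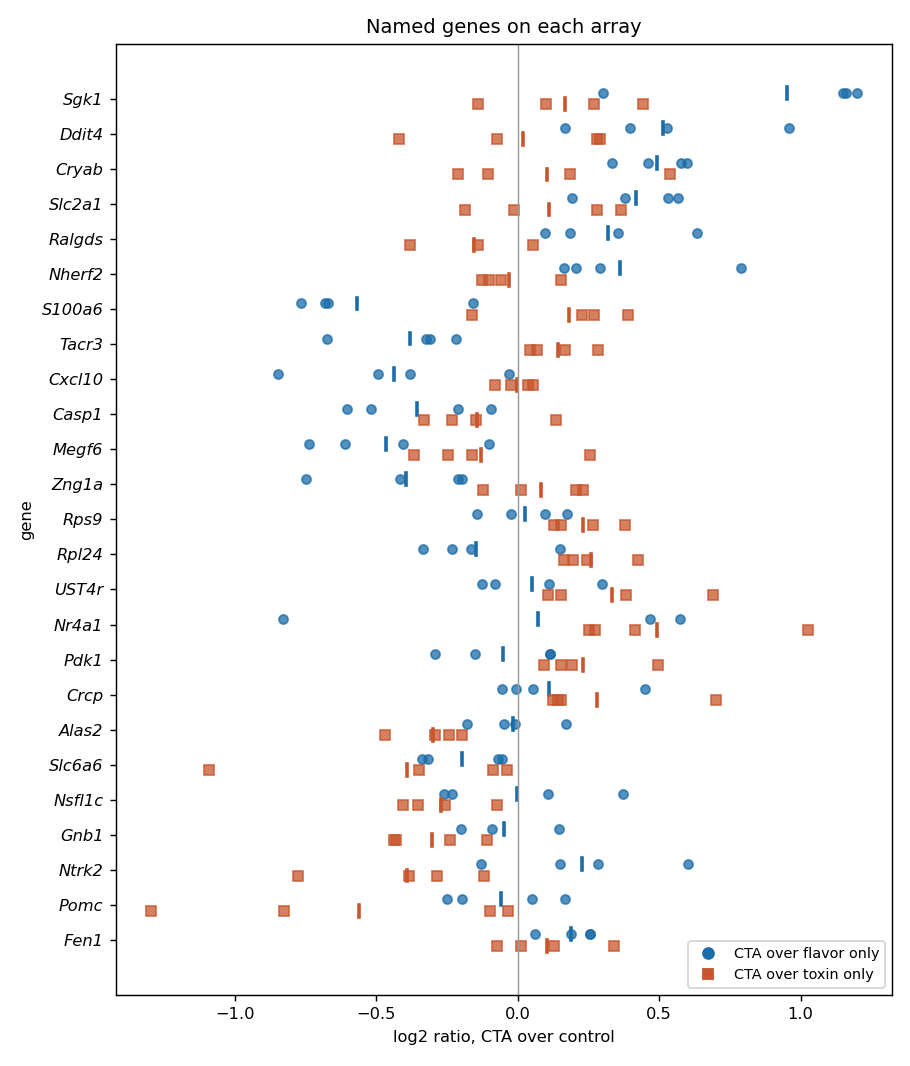
Log2 ratio of CTA over control (x axis) for the named genes (y axis), with 1 circle per CTA versus flavor only array, 1 square per CTA versus toxin only array and a vertical bar at the mean of each set. Sgk1 lies between 0.30 and 1.20 on the 4 flavor only arrays and between -0.14 and 0.44 on the 4 toxin only arrays.

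Against toxin only rats, the comparison that asks what the flavor before LiCl adds to LiCl alone, no single gene of CTA rats passed the adjustment. Among the genes named by smallest unadjusted p with the same sign on 4 of 4 arrays were Nr4a1, Pomc and Ntrk2. Nr4a1, an orphan nuclear receptor of the immediate early class, was at 0.49 ± 0.15. Pomc, the precursor of beta-endorphin and the melanocortins, was at -0.56 ± 0.17, and Ntrk2, the receptor of BDNF, at -0.39 ± 0.12. Errors are limma SE from the fit of all 8 arrays, and the SD over the 4 arrays was 0.36, 0.61 and 0.28 in this order. In limma 0 probes were called, the smallest adjusted p being 0.996, and 433 probes had an unadjusted p under 0.05, where chance gives 985. That count was 220 without toxin only replicate 3, 1077 without replicate 4, 665 without flavor only replicate 2, 801 with scaling between arrays, 290 with the scanner log ratio, 208 without the dye term and 3071 in replicates 3 and 4 only.

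Other positive values were those of UST4r, a membrane transport protein (0.33 ± 0.11), Crcp, a component of the CGRP receptor (0.28 ± 0.10), the ribosomal proteins Rpl24 (0.26 ± 0.08) and Rps9 (0.23 ± 0.06), and Pdk1, a kinase of pyruvate dehydrogenase (0.23 ± 0.08). Other negative values were those of Slc6a6, the taurine transporter (-0.39 ± 0.11), Gnb1, a G protein beta subunit (-0.30 ± 0.09), Alas2, the heme synthesis enzyme of red cells (-0.30 ± 0.07), and Nsfl1c, a cofactor in membrane fusion (-0.27 ± 0.08). Errors are limma SE from the fit of both comparisons together, and the limma adjusted p was 0.996 for each. Within days Nr4a1 was at 0.25, 1.03 and 0.34, and Pomc at -1.29, -0.82 and -0.07. Over the alternatives Pomc ran from -0.83 to -0.07, UST4r from 0.17 to 0.82, Crcp from 0.14 to 0.39, Slc6a6 from -0.50 to -0.19 and Gnb1 from -0.38 to -0.17. UST4r was dim, at a mean log2 intensity of 6.35. Alas2, which is 1 of 3 measured blood markers, fell when adjusted over that list alone, against 0 over all genes.

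Camera called 5 lists in CTA against toxin only rats, and none with an estimated correlation or by fry. Ribosomal protein genes were higher for 25 of 37 members with a median of 0.04 (adjusted p = 0.0136, and adjusted p = 0.807 with an estimated correlation). Oxidative phosphorylation genes were higher for 13 of 19 with a median of 0.05 (adjusted p = 0.0486, and adjusted p = 0.786 with an estimated correlation), among them Ndufa5 at 0.21 ± 0.07 and Cox5a at 0.19 ± 0.07. Immediate early genes, which neurons switch on within minutes of activity, were higher for 22 of 31 with a median of 0.05 (adjusted p = 0.0362, and adjusted p = 0.786 with an estimated correlation), Btg2 being at 0.24 ± 0.10. Glutamate receptor and postsynaptic density genes were lower for 22 of 29 with a median of -0.05 (adjusted p = 0.0136, and adjusted p = 0.786 with an estimated correlation), Camk2b being at -0.44 ± 0.17 and Dlgap1 at -0.21 ± 0.09. Striatum markers were lower for 9 of 12 with a median of -0.17 (adjusted p = 0.0136, and adjusted p = 0.786 with an estimated correlation), Adora2a being at -0.34 ± 0.11. In each of these 5 lists 0 members passed when adjusted over the list alone or over all genes (limma). Their counts at an unadjusted p under 0.05 were 3, 2, 2, 3 and 1.

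Each of these calls was lost without some single toxin only array. Without replicate 4 the ribosomal list (adjusted p = 0.652) and the oxidative phosphorylation list (0.857) were not called, nor was either without replicate 1 (0.126 and 0.118). On the replicate 4 array these lists were at 0.17 and 0.25, and the meninges markers were at -0.45, against -0.09 to 0.35 on the others. Without replicate 3 the immediate early list (0.976), the striatum list (0.674) and the oxidative phosphorylation list (0.490) were not called. On that array the immediate early list was at 0.24, against 0.0075, -0.02 and 0.03 on the others, and markers of choroid plexus were at 0.57, of cortex and hippocampus at 0.32, of thalamus at -0.29 and of striatum at -0.41. Without replicate 2 or replicate 1 the glutamate list was not called (0.756 and 0.118). On the replicate 2 array it was at -0.17, and markers of cortex and hippocampus were at -0.29, against -0.10 to 0.32 on the other toxin only arrays. Within days 1, 2 and 3 the medians were 0.06, -0.02 and 0.09 for ribosomal proteins, -0.03, -0.04 and 0.15 for oxidative phosphorylation, 0.0075, -0.02 and 0.14 for immediate early genes, and -0.03, -0.05 and -0.25 for the striatum markers. The glutamate list was at -0.08, -0.17 and -0.00034 and lost its call with the day as a block (adjusted p = 0.0668). The oxidative phosphorylation call was lost in 17 of 30 alternatives, among them the fits without the dye term (0.0908), with scaling between arrays (0.0966) and with the scanner log ratio (0.0952). The immediate early list was lost with scaling (0.0961) and array weights (0.0571), and the striatum list with the scanner log ratio (0.0663). With the day as a block the lists other than glutamate kept their calls, at adjusted p of 0.000763, 0.00683, 0.00742 and 0.00267 in the order of the day medians above.

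Genes changed in the same direction in both comparisons would mark what CTA adds to either stimulus alone. Of the 19695 probes 0 were called in both (limma), and at an unadjusted p under 0.05 in each, 16 were higher in both, 13 lower in both and 7 opposite. These 29 with the same direction were 15 without toxin only replicate 3, 74 without toxin only replicate 4 and 444 in replicates 3 and 4 only. Comparisons that share CTA pools share chance values. In 20 simulations of unchanged groups, same-numbered arrays were given the consensus correlation of 0.306, as if they shared CTA pools. A mean of 81.1 probes were then higher in both and 76.2 lower in both. That correlation could stand for the dye orientation or the image day as well as for a shared pool. Independent lists of the observed sizes would share 7.67 and 12.8. Across probes, which are not independent replicates, the log2 ratios of the 2 comparisons correlated at -0.0821, against 0.305 simulated, and their covariance was -0.00102 against 0.00286. The simulated values follow from the correlation that was set, so they are no test of shared pools. With CTA over flavor only taken from 2 replicate numbers and CTA over toxin only from the other 2, the correlation ran from -0.309 to -0.0755.

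Toxin only and flavor only rats, compared through CTA, differ in whether they had LiCl or dextrose. Ribosomal protein genes were lower in toxin only rats for 36 of 37 members with a median of -0.19 (adjusted p = 3.6e-08, and adjusted p = 0.503 with an estimated correlation). Oligodendrocyte markers were higher for 13 of 14 with a median of 0.40 (adjusted p = 2.6e-05, and adjusted p = 0.503 with an estimated correlation). Osmotic stress genes were higher for 11 of 12 with a median of 0.21, and cytokine and NF-kB genes lower for 16 of 24 with a median of -0.07 (adjusted p = 0.0345 for each, and adjusted p = 0.503 with an estimated correlation). The osmotic list was not called without flavor only replicate 1 (0.113), 2 (0.0587) or 4 (0.0821) or toxin only replicate 2 (0.0736), without Sgk1 (0.138), with array weights (0.137) or with scaling between arrays (0.0503). The cytokine list was not called without flavor only replicate 2 (0.262) or 3 (0.121) or toxin only replicate 1 (0.115) or 4 (0.0838). The meninges markers, with a median of -0.48 and 6 of 7 lower, were at -0.40, -0.93 and -0.09 on the 3 days. Adjusted over the list alone Sgk1 rose in the osmotic and glucocorticoid lists, at a log2 difference of 0.79 ± 0.21, against 0 over all genes. Of the genes named above, S100a6 was at -0.75 ± 0.16 and Ddit4 at 0.49 ± 0.15, and neither passed (limma adjusted p = 0.712).

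In limma 0 probes were called between toxin only and flavor only, with a smallest adjusted p of 0.712 and 1226 probes at an unadjusted p under 0.05, 411 higher and 815 lower in toxin only. That count was 751 without flavor only replicate 2, 736 without toxin only replicate 3, 2103 without flavor only replicate 4, 594 with the scanner log ratio and 616 without the dye term, where chance gives 985. With the replicate number as a block 0 probes were called (limma), with 2159 at an unadjusted p under 0.05 and a smallest adjusted p of 0.351, and oxidative phosphorylation was called lower as well (adjusted p = 0.0359, against 0.05004 without the block, and adjusted p = 0.503 with an estimated correlation). It was also called with no background subtraction (0.0350), the scanner log ratio (0.0394), the authors' values (0.0344), scaling between arrays (0.0474), a stricter probe filter (0.0351) and the day as a block (0.0425). The authors' values nearly equal those with no background subtraction and add no separate test. By day the ribosomal list was at -0.34, -0.21 and -0.12, the oligodendrocyte list at 0.73, 0.32 and 0.21, the osmotic list at 0.35, 0.18 and 0.14 and the cytokine list at -0.05, -0.20 and -0.07. With the day as a block the adjusted p was 2.6e-08, 3.0e-05, 0.0394 and 0.0394.

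**Figure D2:**
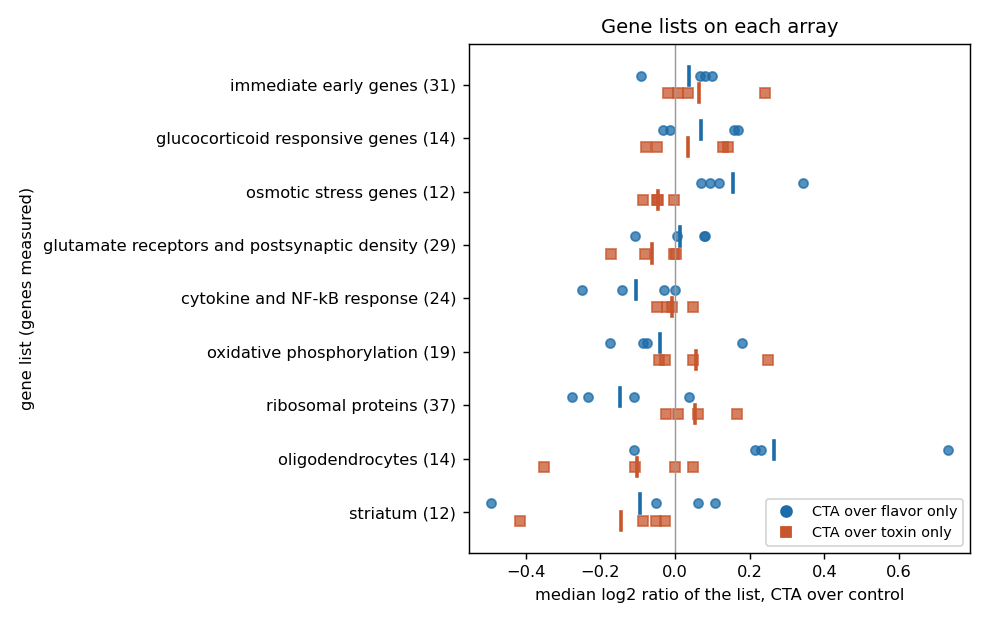
Median log2 ratio of CTA over control (x axis) for 9 gene lists (y axis, genes measured in brackets), with 1 circle per CTA versus flavor only array, 1 square per CTA versus toxin only array and a vertical bar at the mean of each set. The oligodendrocyte list spans -0.11 to 0.73 on the flavor only arrays, and the ribosomal list spans -0.28 to 0.04 there.

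Fen1, the gene in the title of the series, encodes an endonuclease that removes flaps of DNA in replication and base excision repair. It was higher in CTA than in flavor only RNA on 4 of 4 arrays, at 0.25, 0.26, 0.19 and 0.06, with a mean log2 ratio of 0.19 ± 0.09 (SD, n = 4), which is 1.14-fold. The exact two-sided sign-flip test gave p = 0.13, the smallest that 4 arrays allow, and the limma adjusted p was 0.530. Against toxin only RNA it was higher on 3 of 4 arrays, at 0.10 ± 0.18 (SD, n = 4), or 1.07-fold, with an exact p of 0.375 and a limma adjusted p of 0.996. That value was 0.0071 without toxin only replicate 2 and 0.17 without replicate 4. By its unadjusted p Fen1 ranked 1543 of 19695 probes in the first comparison and 3939 in the second. Within days it was at 0.25, 0.26 and 0.13 against flavor only and at 0.13, 0.34 and -0.03 against toxin only. The list of DNA repair and replication genes, which holds Fen1, was not called in either comparison (adjusted p = 0.810 and 0.811).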

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

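The test of spot brightness, the other processings and the fits without single arrays were fixed before their results were seen. Using those fits to weigh an explanation, and the tests by spread over arrays, by toxin only over flavor only and by replicates 3 and 4 only, were chosen only after the result was seen. Single arrays were compared with the other 3 of their comparison in 88 groups of values, and in 9 of them 1 array stood far from the rest. Chance singles out about 1 in 20 groups, or 4.4 here.

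Of the genes, Sgk1 was at 0.30 on the flavor only replicate 3 array and between 1.15 and 1.20 on the others. S100a6 was at -0.16 on the flavor only replicate 4 array and between -0.77 and -0.67 on the others. Crcp was at 0.70 on the toxin only replicate 2 array and between 0.12 and 0.15 on the others. Of the lists, the immediate early genes had a median of -0.0906 on the flavor only replicate 1 array and 0.07 to 0.10 on the others. On the toxin only replicate 3 array the microglia markers had a median of -0.23, against 0.02 to 0.06 elsewhere, and the striatum markers -0.41, against -0.09 to -0.03 elsewhere. The flavor only replicate 1 array had a median green signal of 125, against 184 to 194. Spots marked non-uniform numbered 2236 on the flavor only replicate 4 array, against 120 to 267, and 264 on the toxin only replicate 2 array, against 70 to 93.

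The comparisons differed for 4 lists, as toxin only over flavor only: ribosomal proteins at a median of -0.19 (adjusted p = 3.6e-08), oligodendrocyte markers at 0.40 (2.6e-05), osmotic stress genes at 0.21 (0.0345) and cytokine and NF-kB genes at -0.0725 (0.0345). With an estimated correlation the adjusted p was 0.503 for each.

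Glucocorticoid responsive genes lay higher in CTA than in flavor only RNA (adjusted p = 0.00819, 0.530 with an estimated correlation, and 0.000172 to 0.730 over the alternatives), and 3 explanations were tested. Background correction or normalization was argued against as the whole cause, because without background subtraction, with the scanner log ratio and with the authors' values the highest adjusted p was 0.00942, the list being higher in each. The authors' values nearly equal the ratios without background subtraction, so they add no separate test. A single array remains a possible explanation, because without flavor only replicate 4 the adjusted p was 0.730, while without replicate 1, 2 or 3 it was 0.000495 to 0.00281. LiCl, which CTA rats had and flavor only rats had not, could not be told apart from the pairing of flavor and LiCl. The list gave an adjusted p of 0.503 for toxin only over flavor only with an estimated correlation. That test could not decide, because under this setting no list was called in any comparison. With the preset correlation the camera adjusted p was 0.119. The list was called higher there without flavor only replicate 1 (0.0291) or toxin only replicate 3 (0.0394), and in replicates 3 and 4 only (0.0146). Toxin only and flavor only rats differ in dextrose as well as in LiCl, so even a direct comparison of them would not isolate LiCl. No group had water and saline.

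Oligodendrocyte markers lay higher in CTA than in flavor only RNA (adjusted p = 2.9e-06, 0.530 with an estimated correlation, which is the highest over the alternatives, and 1.5e-09 at the lowest), and 3 explanations were tested. Unequal tissue makeup of single pools, such as more white matter in some punches, stays open: the list median spread over arrays by 0.263 (mean SD), at percentile 100 of 10000 random lists, the highest of which was 0.196, but genes expressed together spread more than random genes in any case. The lists of meninges (0.372, 7 genes), choroid plexus (0.311, 12), endothelium (0.229, 7) and striatum (0.227, 12) markers also spread widely. They hold fewer genes than the 14 of this list, so the random lists give no limit for them. A single array could not be ruled out, because without flavor only replicate 1 the adjusted p was 0.0498, just inside the threshold, and without replicate 2, 3 or 4 it was at most 7.9e-06. LiCl stays open, with an adjusted p of 0.503 for toxin only over flavor only with an estimated correlation. That test could not decide, because under this setting no list was called in any comparison. With the preset correlation the list was higher in toxin only (camera adjusted p = 2.6e-05), but that comparison holds the same flavor only arrays. In CTA over toxin only, where both sides had LiCl, the list was at -0.06 (0.464).

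Ribosomal protein genes lay lower in CTA than in flavor only RNA (adjusted p = 1.5e-06, 0.530 with an estimated correlation, and 7.1e-09 to 0.575 over the alternatives), and 3 explanations were tested. Spot brightness could not be ruled out. The list median of -0.14 lay at percentile 0 of random lists drawn by brightness, the lowest of which was -0.10. Genes expressed together spread more than random genes, so this percentile cannot decide. The list was also far brighter than all genes (mean log2 intensity 12.0 against 7.98), and how closely the random lists matched it was not measured. Those random lists had a median of -0.0033, so brightness as matched there did not by itself lower a list. A single array was argued against as the whole cause, because the highest adjusted p without 1 of the 4 flavor only arrays was 0.00538. LiCl stays open, with an adjusted p of 0.503 for toxin only over flavor only with an estimated correlation. That test could not decide, because under this setting no list was called in any comparison. With the preset correlation the list was lower in toxin only (camera adjusted p = 3.6e-08), but that comparison holds the same flavor only arrays. In CTA over toxin only, where both sides had LiCl, the list was at 0.04 (0.0136). In replicates 3 and 4 only the adjusted p was 0.575, and the makeup of the pools was not tested for this list.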

How the results depend on the processing

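The alternatives with only replicates 3 and 4, with non-uniform spots kept, with lists against all tested probes, with wider naming, without both arrays of a replicate and without Sgk1 were chosen only after the results were seen. The named gene values kept direction and side of the threshold in 526 of 527 alternatives for 24 values, though sizes moved. The other was Sgk1 in CTA versus flavor only without flavor only replicate 3 (adjusted p = 0.0126). The choice of these genes largely fixed that count, because each had the same sign on all 4 arrays and none was called in the main fit. The 14 called lists kept theirs in 330 of 420 alternatives, lost the call in 88 and turned in 2. Some of these alternatives could hardly change a call, such as leaving Sgk1 out of lists that do not hold it. The authors' values also nearly repeat those without background subtraction, so the 330 overstates how firm the calls are. Aquantile normalization leaves the ratios as they are and is not counted.

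For CTA versus flavor only, 1 probe instead of 0 was called with array weights, with the replicate block, with the image day as a block and at an adjusted p under 0.10, and 0 to 1 with an array left out. The unadjusted counts, 1848 for CTA versus flavor only, 433 for CTA versus toxin only, 1226 for toxin only versus flavor only and 29 in both, follow from the absence of adjustment. The comparison's own 4 arrays give no value for toxin only versus flavor only.

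Lists called in CTA versus flavor only numbered 5, with a range of 4 to 8 without single arrays, 3 to 7 without both arrays of a replicate, and 3 without Sgk1, a shared member. Lists called in CTA versus toxin only numbered 5, with 3 under the scanner log ratio, between-array scaling, only the comparison's 4 arrays, non-uniform spots kept or lists against all tested probes, 3 to 5 without single arrays and 1 to 3 without both arrays of a replicate. Lists called for toxin only versus flavor only numbered 4, with 2 to 9 without single arrays, 3 to 6 without both arrays of a replicate and 7 at an unadjusted p under 0.05. In each of the 3, 0 lists were called with a fold over 1.5 also required, with an estimated correlation, and by fry, directional or mixed. Apart from arrays left out and thresholds, the cause was not tested.

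In CTA versus toxin only the glutamate list turned to higher in replicates 3 and 4 only (adjusted p = 0.737), and the immediate early list to lower without replicate 3 (0.980), its range without a replicate being 0.000897 to 0.980. Fen1 in CTA versus toxin only was at -0.0301 in replicates 3 and 4 only. Fewer arrays enter each. With the replicate number as a block, oxidative phosphorylation was added to the lists of toxin only versus flavor only (adjusted p = 0.0359), as it was with no block under the authors' values (0.0344), and besides this and the 1 probe above the block changed no other call. The median signal was as low as 2.60 times background, which limits what dim probes can show.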

Other observations

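The counts over other groupings of the arrays were fixed before they were seen, and the probes chosen by description in this part were picked only after their values were seen.

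Of the list members not named in the report, values in CTA over flavor only included those of the interneuron marker Pvalb (0.41 ± 0.11), the astrocyte marker Gfap (0.29 ± 0.09), the vesicular GABA transporter Slc32a1 (-0.51 ± 0.15, on 3 arrays) and the adrenergic receptor Adra1a (-0.46 ± 0.11, on 3 arrays). Ttr, made in choroid plexus, was at 0.31 ± 0.13 in CTA over flavor only and 0.41 ± 0.13 in CTA over toxin only. Corticotropin releasing hormone, Crh, was at -0.23 ± 0.08 in CTA over toxin only. Errors are limma SE from the fit of both comparisons together, with 4 arrays in the comparison except where given.

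Some probes were named by description alone. A probe like FK506 binding protein 5, a chaperone induced by glucocorticoids (A_42_P493879), was at 0.68 ± 0.09 in CTA over flavor only (limma SE, 4 arrays). Another of the same description, A_43_P18969, was at 0.21 ± 0.10. A probe for BTE binding protein, a name also used for Klf9 (A_42_P786109), was at 0.50 ± 0.10, and the Klf9 probe at 0.24 ± 0.10. A hemoglobin alpha-like probe, A_43_P14316, was at -0.69 ± 0.11 in CTA over toxin only and -0.47 ± 0.11 in CTA over flavor only. None of these passed the adjustment in limma.

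Turning the sign of some of the 4 arrays gives 8 patterns, too few for a share under 0.05. Most of these patterns do not hold both dye orientations equally, as the real one does, so they are not like it. The others with equal orientations held 1181 and 1734 probes in CTA versus flavor only, with 6 and 2 lists. In CTA versus toxin only they held 1043 and 414 probes, with 4 and 4 lists. In CTA versus flavor only, 2 of 8 patterns held as many probes at an unadjusted p under 0.05 as the real 1848, the highest other holding 3346, and 3 of 8 held as many called lists as the real 5, the highest other holding 6. In CTA versus toxin only, 5 of 8 held as many probes as the real 433, the highest other holding 1476, and 2 of 8 held as many lists as the real 5, the highest other holding 5. For probes with the same direction in both comparisons, 7 of 7 patterns of the replicate numbers that could be fitted held as many as the real 29, the highest other holding 1148. The counts include the real pattern.

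Splitting the 8 arrays in other ways gave as many probes as the real 1226 for toxin only versus flavor only in 11 of 34 splits, the real one included, the highest other holding 2819, and as many lists as the real 4 in 16 of 34, the highest other holding 9. Over these splits chance is not excluded. Apart from the real split, each of those with as many probes keeps at least 2 same-numbered pairs together, which the real split does not. Of the 8 splits that part every pair, too few for a share under 0.05, the real one held the most probes, the highest other holding 805, and 3 of 8 held as many lists, the highest other holding 5. Replicates 1 and 2 against 3 and 4, a split by image day, gave 1993 probes and 8 lists. Toxin only versus flavor only gave 1902 probes and 5 lists with the day as a block, and 2979 probes and 3 lists in replicates 3 and 4 only.

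Lists without a call are given as the median in CTA over flavor only, then in CTA over toxin only, with camera adjusted p in the same order. DNA repair and replication genes were at -0.04 and -0.0060 (0.810, 0.811), lithium, inositol and GSK3 targets at 0.08 and -0.04 (0.243, 0.654), and heat shock genes at 0.01 and -0.03 (0.819, 0.676). The GABA system was at -0.04 and -0.03 (0.955, 0.654), neuropeptides at -0.05 and -0.00435 (0.105, 0.676), and monoamine and cannabinoid receptors at 0.02 and -0.03 (0.496, 0.676). Markers of neurons were at 0.04 and -0.03 (0.800, 0.464), of astrocytes at -0.02 and -0.05 (0.819, 0.464), and of endothelium at 0.0050 and -0.0027 (0.819, 0.676). Choroid plexus markers were at 0.11 and 0.09 (0.0815, 0.424), hypothalamus at 0.03 and -0.04 (0.800, 0.424), thalamus at -0.03 and 0.05 (0.800, 0.464), and cortex and hippocampus at 0.08 and -0.01 (0.432, 0.676).

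Some of these lists were called under alternatives. In CTA over flavor only, choroid plexus markers were called higher with the day as a block (0.0275), with scaling between arrays (0.00966) and without flavor only replicate 2 (0.00725) or 3 (0.000423) or toxin only replicate 1 (0.0490), striatum markers lower with array weights (0.0265) and without flavor only replicate 1 (0.0276) or 2 (0.00809), and neuropeptides lower with scaling (0.0227). Without flavor only replicate 1, immediate early genes and the cortex and hippocampus markers were called higher (0.0276 each), and without replicate 4 meninges markers lower (0.0451). In CTA over toxin only, choroid plexus markers were called higher without toxin only replicate 1 (0.0134) or 2 (0.0361), and without replicate 3 thalamus markers were called higher (0.0219) and cortex and hippocampus markers lower (0.00737).

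Of the lists called in only 1 of these comparisons, the other gave 0.08 for glucocorticoid responsive genes (0.464), 0.02 for osmotic stress genes (0.924), 0.02 for cytokine and NF-kB genes (0.811) and -0.06 for oligodendrocyte markers (0.464) in CTA over toxin only. In CTA over flavor only, immediate early genes were at -0.0029 (0.800), glutamate receptors at 0.01 (0.800), oxidative phosphorylation at -0.04 (0.432) and striatum markers at -0.14 (0.229). Too small for a set test were the circadian clock (0.03, then -0.05), microglia (0.01, then -0.05), blood (-0.02, then 0.10) and meninges (-0.40, then 0.08) lists. All 7 meninges genes were lower in CTA than in flavor only RNA, at array medians of -0.05, -0.69, -0.70 and -0.02. The sign of the list median and of the camera direction differed in CTA over flavor only for the immediate early, GABA, astrocyte and endothelium lists and in CTA over toxin only for the DNA repair and endothelium lists, none of them called there.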
